A study of Mus musculus with 4 samples.

How the data were processed

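Genomic DNA of 4 liver tumours, 1 per mouse, was compared with pooled reference DNA from 3 mice on Agilent mouse arrays. Per the labels, tumour DNA carried Cy5 and reference DNA Cy3. The deposited log10 ratios are red over green after spatial detrending, background subtraction and linear dye scaling, per the file headers; the lowess dye term was 0. Agilent Feature Extraction 10.7.3.1 is named in the submitters' processing notes. The deposited intensity values, per the file headers, are the processed and the raw signals of both channels with the local background. Probe positions are those of the files, on mm9 (NCBI 37). The value table of the whole series, also deposited on the log10 scale, matched the ratios of each array within rounding (0.5% of the value) at all 180880 features, so its scale, centring and direction are known; its column medians were -0.0011, 0.0018, 0.00056 and 0.0032. The files hold a slide code: tumours 1 and 4 shared a slide, and the other two had a slide each.

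Ratios were turned to log2, so that positive values mean more tumour DNA. Control spots and spots marked as outliers (93 to 126 per array) were left out, the 5 spots of each of 1000 repeated probes were averaged, and each array was centred on the median of its autosomal probes, with no further dye or intensity normalization. The 170305 probes were 60 bases long in the median. Repeated spots of a probe had an SD of 0.07, 0.11, 0.11 and 0.07 in tumours 1 to 4. Median red signals over background were 1163, 527.9, 522.2 and 1286 and green signals 658.2, 348.2, 164.6 and 577.4.

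Gene names are those of the array design; 20749 names were used, of which 12789 are current symbols and 1831 older symbols in a RefSeq table of another build, which served for names only. No gene annotation of mm9 was used, so exons and introns are not given. A gene's value is the mean over probes from its first to its last named probe plus 50 kb on each side, so neighbouring genes share probes. Where a probe was not well above background in the tumour channel, an upper bound on its ratio was set with the lowest red signal among spots well above background.

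Segments were found per chromosome by exact penalised least squares, coded for this work, with a penalty of 4 times the log of the number of probes times the noise variance, taken from the differences between neighbouring probes. Segments of at least 5 probes with a mean of at least 0.2 were called gained, and those at -0.2 or below lost. Bins of 1 Mb with at least 5 probes were called when over 50% of their probes were. Mean log2 ratios of chromosomes, bins and genes were tested against 0 with limma 3.58.1 (moderated intercept, Benjamini-Hochberg under 0.05) in R 4.3.3. Two-sided exact sign-flip tests over 4 tumours cannot go below 0.13. Recurrence, similarity and the autosomal members of gene lists were tested with 10000 random circular shifts, whose smallest p is 1e-04. All tumours formed 1 group. The labels say that the tumours came from separate mice.

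Genes were named by a rule fixed with the tests, lists and alternatives before the data were examined: Trp53; members of each list inside segments called the same way in at least 2 of 4 tumours; per tumour up to 3 gained and 3 lost segments under 5 Mb with the most extreme means, each with up to 3 genes; and chromosomes past the test or called over at least 90% of their probes in any tumour. This named 27 genes, and 1 small segment that it also picked counts in the shares but is not reported here. Other genes are given as ends of a list's range, as members past a list's own adjustment or as examples, chosen after their values were seen.

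Alternatives were normexp background correction (offset 50), centring on the mode, the value table, only probes well above background (125 probes removed), GC correction by lowess on the probe sequence, each tumour left out, other bin sizes, thresholds, penalties, flanks and numbers of tumours, and circular binary segmentation. Added after the data were seen were autosomes only, similarity without chromosomes 9, 12 and 15 or without bins of small called segments, and Igh relative to its chromosome.

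The methods were tested on simulated data. Of simulated segments of 500 probes with a log2 change of 0.3 on 170305 probes, 100% were called at the noise of each tumour; of those of 50 probes, 5% were at the noise of tumour 1, 0% at that of tumour 2, 100% at that of tumour 3 and 95% at that of tumour 4. Of segments of 10 probes with a change of 1, 60% were called at the noise of tumour 2 and 100% at that of the others. The simulated change was the same at every probe of a segment, unlike in the deep losses measured here. An 11-probe stretch of chromosome 11 at -5.05 in tumour 3 and -4.11 in tumour 4 was called in neither. Y was called lost over 73.0% of its probes in tumour 1. These shares therefore do not hold for deep losses with uneven probes. Among 2541 simulated bins with 200 changed, limma called 32% of those changed by 0.1, 74% at 0.2 and 100% at 0.4. Of 200 unchanged lists, 3% had a p under 0.05, and so had 11% of 100 sets of independent random blocks in the recurrence test.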

Results

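Copy number was profiled by array comparative genomic hybridisation in 4 liver tumours, each from a separate mouse on a C57BL/6J background with Trp53 lost in the liver. Trp53 encodes the p53 tumour suppressor. Tumour DNA (red dye) was hybridised together with reference DNA (green dye), and a positive log2 ratio means more DNA in the tumour than in the reference. The reference was a pool of spleen DNA from 3 littermates of the same sex per the series' design, whereas the labelling protocol calls it liver; both channels are labelled Trp53-/- and male. Each array carried 180880 spots, of which 174305 were genomic, and after averaging of repeated spots 170305 probes with a median spacing of 10.8 kb remained. At least 99.96% of the genomic spots were well above background in both channels. The log2 ratio correlated with the GC content of the probe at 0.218, 0.131, -0.049 and 0.130 in tumours 1 to 4. The noise SD between neighbouring probes was 0.26 in tumour 1, 0.32 in tumour 2, 0.16 in tumour 3 and 0.17 in tumour 4, and the spread metric of tumour 2 was marked out of range in its file. There was 1 array per tumour and no control tumour, so the ratio was tested against 0, which leaves out the spread of the reference DNA, and the number of arrays limits the precision.

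The targeted gene was looked at first. The 12 probes within 50 kb of Trp53 (chromosome 11, mm9) averaged near the reference level, with a mean log2 ratio of 0.12 ± 0.10 (SE over probes) in tumour 1, -0.04 ± 0.11 in tumour 2, -0.05 ± 0.05 in tumour 3 and 0.03 ± 0.06 in tumour 4. Their mean was 0.01 ± 0.08 (SD, n = 4), and limma gave an adjusted p of 0.87. A pair of probes fell in the gene itself, at 69395366 to 69395425 and 69404685 to 69404744. Their mean was 0.52 in tumour 1, 0.32 in tumour 2, -0.16 in tumour 3 and 0.29 in tumour 4. This was above the calling threshold of 0.2 in 3 of 4 tumours, in the same order as the correlations with probe GC. Averaged over the tumours the pair was at 0.24, and at 0.21 after GC correction. For these probes limma gave an unadjusted p of 0.059 (adjusted p = 0.26), and the two-sided exact sign-flip p was 0.25, in a test that cannot go below 0.13 with 4 tumours. The labels do not say which part of the gene was deleted, and these probes may lie outside it, so they do not check the genotype labels.

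Whole-chromosome changes centred on chromosomes 9, 12 and 15, and their size differed widely between tumours. Chromosome 15 had a mean log2 ratio of 0.27 ± 0.01 (SE over 1 Mb bins) in tumour 1, 0.28 ± 0.01 in tumour 2 and 0.09 ± 0.01 in tumour 3, against -0.0036 ± 0.0037 in tumour 4, and it was called gained over 100% of its probes in tumours 1 and 2. Chromosome 9 was at -0.31 ± 0.01, -0.19 ± 0.01, -0.10 ± 0.0044 and -0.02 ± 0.0034 in tumours 1 to 4. It was called lost over 99.98% of its probes in tumour 1. Chromosome 12 lay at -0.29 ± 0.01, -0.23 ± 0.01, -0.07 ± 0.01 and -0.02 ± 0.0047. Its probes were called lost at 98.3% in tumour 2 and 86.2% in tumour 1. Tumour 4 had means below 0 on every autosome, down to -0.034 on chromosome 11. Its chromosomes 9 and 12 were therefore not lower than its other autosomes. In tumour 1 chromosome 15 had a step: 0.21 from 3114799 to 58125568 and 0.32 from 58139969 to 103460314. Over these parts tumour 2 was at 0.27 and 0.30, tumour 3 at 0.12 and 0.05 and tumour 4 at -0.01 and 0.01. The size of the step had the same order over the tumours as the correlations with probe GC. It is therefore not shown to belong to the gain. Tumour 2 alone also had a lower chromosome 13 (-0.20 ± 0.01) and values near 0.09 on chromosomes 6, 8 and 18 and 0.10 on chromosome 19, none of them called. Averaged over the tumours, chromosome 9 was at -0.16 ± 0.12 (SD, n = 4), chromosome 12 at -0.15 ± 0.13 and chromosome 15 at 0.16 ± 0.14. With limma, 0 of the 21 chromosomes passed the adjusted threshold of 0.05 (adjusted p = 0.36 for each of the 3), and 1 had an unadjusted p under 0.05.

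**Figure D1:**
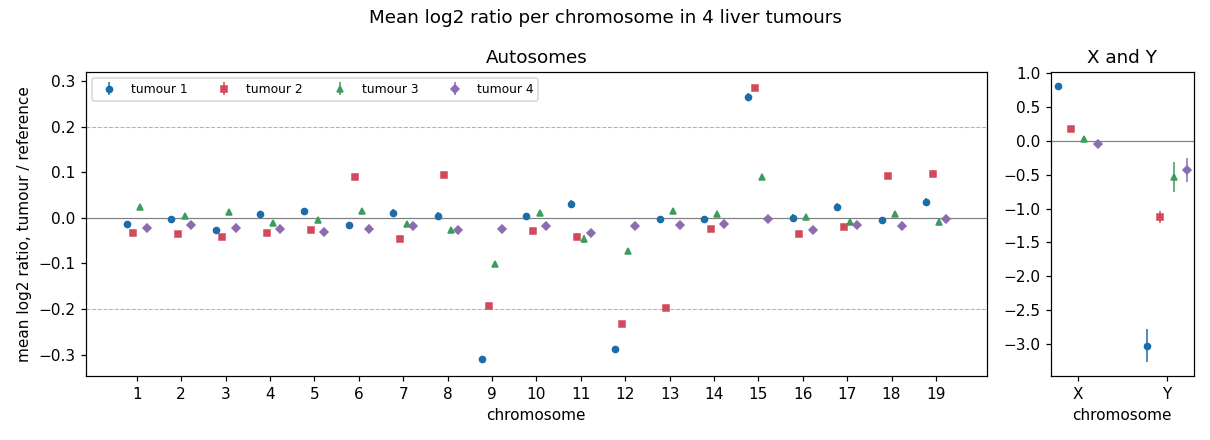
Mean log2 ratio of each chromosome (x axis) in the 4 tumours, with tumour DNA over reference DNA on the y axis; points are tumours, bars are the SE over 1 Mb bins, and dashed lines mark the calling threshold of 0.2. Chromosome 15 reached 0.28 in tumour 2, chromosome 9 reached -0.31 in tumour 1, and tumour 4 stayed near 0 on all autosomes.

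The sex chromosomes set tumour 1 apart. In this tumour, labelled male, X was raised over its whole length, with a mean log2 ratio of 0.81 ± 0.01 (SE over bins) and 99.98% of its probes in gained segments, while Y was at -3.03 ± 0.24. At 55 of its 122 probes the tumour channel was not well above background, and with the lowest measurable signal there Y was at -2.42, at least 5.35-fold lower. The Y genes followed: Kdm5d and Uty, which encode histone demethylases, were at -3.58 and -3.29 in tumour 1, and Usp9y, which encodes a deubiquitinase, was at -3.58. With dim probes at their bounds, the 3 were at -2.25, -2.71 and -2.64. In tumour 2 X was at 0.18 and Y at -1.12 ± 0.09, with 100% of Y probes called lost; Uty was at -0.98, Usp9y at -1.06 and Kdm5d at -1.11. Tumour 3 had X at 0.04 and Y at -0.53, and tumour 4 had X at -0.05 and Y at -0.43, means pulled down by a short stretch that was low in all 4 tumours. Over the 76 probes with Uty and Usp9y they were at -0.23 and -0.19. Averaged over the tumours, Y was at -1.28, against -0.61 under normexp correction, -0.78 with only probes well above background and -0.69 without tumour 1. Neither X (adjusted p = 0.52, limma) nor Y (adjusted p = 0.36) passed the test over the 4 tumours.

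The share of the genome in called segments ranged over 2 orders of size. Gained or lost segments held 18.0% of the probes in tumour 1 (9.17% gained, 8.82% lost), 8.13% in tumour 2 (3.92% gained, 4.20% lost), 0.24% in tumour 3 and 0.13% in tumour 4. The mean was 6.62% ± 8.45 (SD, n = 4), and it dropped to 2.83% without tumour 1. Chromosomes 9, 12, 15 and X made up most of the share in tumour 1, and chromosomes 12 and 15 in tumour 2; on autosomes alone, an alternative chosen after the data were seen, tumour 1 had 13.5% and tumour 2 had 8.50%. The number of called segments was 26, 7, 8 and 10 in tumours 1 to 4. In tumour 1 most were pieces of chromosomes 9, 12, 15, X and Y, so they do not count separate events. The shares depended on the threshold: at 0.1 they were 21.7%, 23.4%, 8.25% and 0.51% in tumours 1 to 4, with tumour 2 above tumour 1, and at 0.3 they were 13.3%, 0.08%, 0.10% and 0.12%. Normexp background correction took tumour 2 to 17.7%, near the 18.9% of tumour 1, and tumour 3 to 5.29%, with a mean of 10.5%. Centring on the mode gave 12.6% and circular binary segmentation 11.8% in tumour 2.

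Shared regions of gain and loss were counted in 1 Mb bins. None of the 2388 autosomal bins was gained, or lost, in at least 3 of the 4 tumours. A bin is called only when most of its probes are, so segments much shorter than 1 Mb can go uncounted. The region of EG214403 (9 probes) was called gained in 3 of the 4 tumours, without a bin called. Likewise, the region of Entpd4 (23 probes) was called lost in 3 of the 4. In at least 2 of 4 tumours, 102 bins were gained, 101 of them on chromosome 15, and 102 were lost, 100 of them on chromosome 12 and 2 on chromosome 9. One-sided permutation tests with 10000 circular shifts gave a p of 1e-04 for the gained bins, the smallest they can give, where 4.55 were reached on average by chance, and 0.013 for the lost bins, where chance gave 10.8. On simulated independent tumours this test gave a p under 0.05 in 11% of sets, more than it should. The value for lost bins is therefore weak. The shifts also ignored chromosome ends, so they seldom laid a whole changed chromosome of 1 tumour over that of another. Nearly all shared bins lay on 1 chromosome per direction. Both p-values therefore do not measure how often 2 tumours change the same chromosome by chance. With the calling threshold at 0.1, 77 bins were gained and 102 lost in at least 3 of 4 tumours. Their permutation p-values were 1e-04 and 0.0003, from shifts with the same limit.

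Profiles of the tumours were compared over the autosomal bins. The mean of the 6 pairwise Pearson correlations was 0.33, with a permutation p of 1e-04, the smallest the shifts can give; bins are not independent replicates. The shifts ignored chromosome ends. They also do not allow for a shared reference or for probe effects common to all arrays. Either would raise the correlation without any shared change in the tumours. Tumours 1 and 2 had the highest correlation at 0.78, followed by tumours 1 and 4 at 0.38 and tumours 2 and 4 at 0.38, tumours 2 and 3 at 0.24, tumours 1 and 3 at 0.10 and tumours 3 and 4 at 0.09. Over the means of the 19 autosomes the order differed, with tumours 1 and 3 highest at 0.86, then tumours 1 and 2 at 0.79 and tumours 2 and 3 at 0.68. The mean dropped to 0.19 without tumour 2 and reached 0.51 without tumour 3. It was 0.15 (permutation p = 1e-04) without chromosomes 9, 12 and 15, an alternative chosen after the data were seen. Over single probes the correlation was 0.84 between tumours 1 and 2, 0.69 between tumour 4 and each of these, and 0.09, 0.19 and 0.32 between tumour 3 and tumours 1, 2 and 4. Tumour 4, with 0.13% of its probes in called segments, still reached 0.69, so the correlations do not show shared tumour changes by themselves.

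Small segments included several that differed from the reference in the same direction in all 4 tumours. The lowest was a stretch of chromosome 11 (70989862 to 71107103, 11 probes) that holds Nlrp1c and part of Nlrp1b, genes of inflammasome sensors, and DQ117583, a transcript name of the array. The whole stretch was called lost in tumour 2, and 7 of its probes in tumour 1. It had no call in tumours 3 and 4 and is not in their altered shares. Its mean log2 ratio was -3.74 ± 0.39 (SE over probes) in tumour 1, -4.37 ± 0.42 in tumour 2, -5.05 ± 0.39 in tumour 3 and -4.11 ± 0.41 in tumour 4. At 3 of its probes the tumour channel was not well above background on any array, so these values are bounds there; with the lowest measurable signal in place of dim probes, the tumours were at least 11.2-fold, 12.7-fold, 18.5-fold and 14.6-fold lower than the reference, in that order. On chromosome 14, 23 probes from 69876584 to 70090608 had -0.52, -0.57, -0.60 and -0.59 in tumours 1 to 4; they cover Entpd4, which encodes a nucleotide-hydrolysing enzyme, Loxl2, a lysyl oxidase gene, and Slc25a37, a mitochondrial iron importer gene. On chromosome 1, 9 probes from 141582304 to 141678786 with the names EG214403 and BC013664 had 0.71, 0.69, 0.92 and 0.78. At Raet1a on chromosome 10, a gene of a ligand of natural killer cell receptors, 12 probes had 0.64, 0.50, 0.48 and 0.54, and at 4922505G16Rik on chromosome 2, 5 probes had -0.68, -0.84, -0.94 and -0.92. A stretch of Y without gene names (972031 to 1119793) had -3.41, -3.60, -4.60 and -3.50, but 2 of its 5 probes were dim in tumours 1, 2 and 4 and all 5 in tumour 3, so these are bounds: at least 7.35-fold, 7.03-fold, 11.7-fold and 9.53-fold lower.

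**Figure D2:**
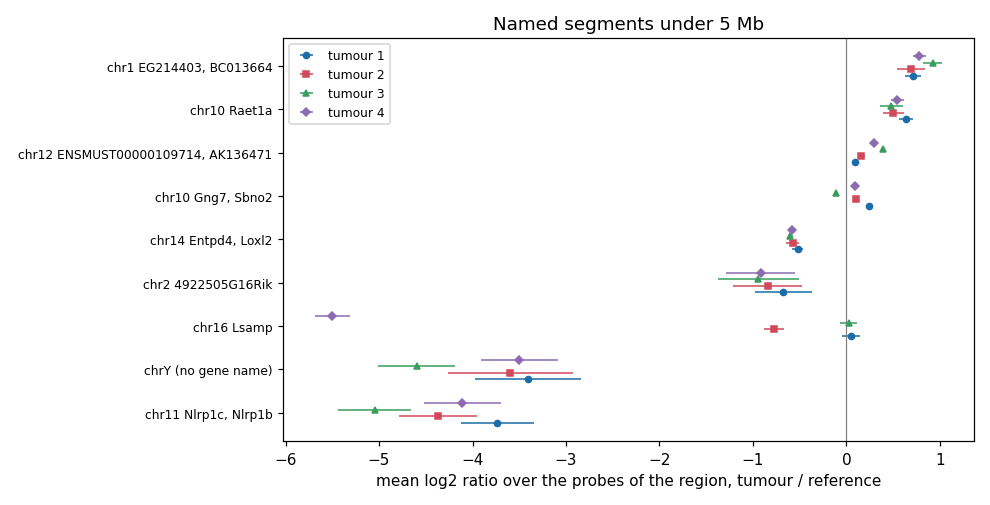
Mean log2 ratio (x axis) of each named segment under 5 Mb (y axis, with chromosome and gene names of the array) in the 4 tumours; points are tumours and bars the SE over probes. The regions of EG214403, Raet1a, Entpd4 and 4922505G16Rik have similar values in all 4 tumours. That of Nlrp1c runs from -3.74 to -5.05, and Lsamp reaches -5.50 in tumour 4 alone.

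Other small segments differed between tumours. Within Lsamp on chromosome 16, a large gene of a neuronal cell adhesion molecule, 7 probes from 41738764 to 41794655 were at -5.50 ± 0.19 (SE over probes) in tumour 4 and at -0.78 ± 0.11 in tumour 2, against 0.05 and 0.02 in tumours 1 and 3. At 5 of these probes the signal of tumour 4 was not well above background, and the tumour was at least 24.0-fold lower than the reference. Over a longer low run of 11 probes (41702133 to 41794655) tumour 4 was at -4.74 ± 0.60, at least 15.6-fold lower. A gene-rich stretch of chromosome 10 from 79008963 to 80986185, with Gng7, Sbno2 and Onecut3, was called gained in tumour 1. It was at 0.24, 0.11, -0.11 and 0.09 in tumours 1 to 4, in the same order as the correlations with probe GC. After GC correction these genes had means over the tumours of 0.10, 0.13 and 0.09, against 0.08, 0.13 and 0.09 before. With 1 array per tumour, differences between tumours and between arrays cannot be told apart here.

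**Figure D3:**
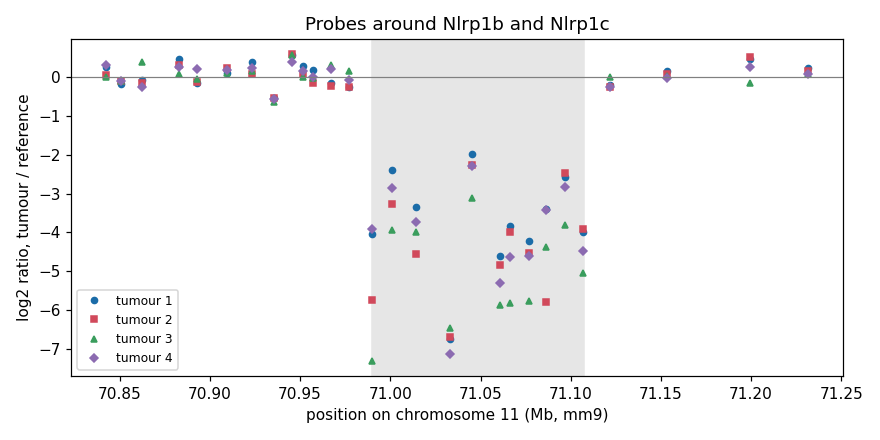
Log2 ratio of each probe (y axis) by its position on chromosome 11 in Mb of mm9 (x axis) around Nlrp1b and Nlrp1c. Each point is a probe in a tumour. The shaded stretch was called lost as a whole in tumour 2, in part in tumour 1 and not in tumours 3 and 4. The 11 probes inside it average between -3.74 and -5.05 in the 4 tumours.

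With limma, 1 of 2541 bins passed the adjusted threshold of 0.05, the bin of chromosome 11 from 71000001 to 72000000, which was lower by a mean log2 ratio of -0.70 ± 0.04 (SE, adjusted p = 0.046) in 4 of 4 tumours; 296 bins had an unadjusted p under 0.05. Of 20756 gene items, 9 passed, 8 of them lower and 1 higher, and 4261 had an unadjusted p under 0.05. Nlrp1c fell by -3.93 ± 0.14 (SE, adjusted p = 0.0019), DQ117583 by -4.37 ± 0.17 and Nlrp1b by -2.38 ± 0.11, the last a mean over probes inside and outside the low stretch. The size of these 3 rests on dim probes. Under normexp correction they were at -2.03, -2.48 and -1.35, and with only probes well above background at -2.35, -3.14 and -0.92, all past the threshold. Entpd4 fell by -0.60 ± 0.03 (adjusted p = 0.0035) and Loxl2 by -0.37 ± 0.03, and their neighbours AK046150, AK031288 and BC086315, which the naming rule does not cover, fell by -0.61, -0.57 and -0.55. Under normexp correction Entpd4 (-0.75, adjusted p = 0.062) and Loxl2 (-0.49, adjusted p = 0.082) did not pass. Loxl2 did not pass without any 1 of the tumours (-0.38 to -0.36, adjusted p = 0.087 to 0.63). EG214403 rose by 0.65 ± 0.05 (adjusted p = 0.023), and did not pass with no flank (0.74, adjusted p = 0.069) or without tumour 4 (0.64, adjusted p = 0.16). Raet1a (0.45, adjusted p = 0.058), Slc25a37 (-0.35, adjusted p = 0.059), BC013664 (0.18, adjusted p = 0.19) and 4922505G16Rik (-0.29, adjusted p = 0.16) missed the threshold. Raet1a passed under normexp, mode centring and GC correction (adjusted p = 0.048, 0.049 and 0.033), Slc25a37 under mode centring, GC correction and no flank (0.044, 0.028 and 0.030), and 4922505G16Rik with no flank (-0.60, adjusted p = 0.040). The count of genes was 0 without tumour 2 and 3 without tumour 4, and the bin did not pass without tumour 2, 3 or 4. The ratios stayed near their size. Without tumour 2, Nlrp1c was at -3.93, Entpd4 at -0.59 and EG214403 at 0.68.

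Among 35 measured genes of the oncogene list, fixed before the data were examined, none passed over all genes and 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05; 17 had a positive mean and 18 a negative mean. Their range ran from Birc3, an inhibitor of apoptosis on chromosome 9, at -0.15 ± 0.12 (SD, n = 4), to Fgf15, a growth factor gene, at 0.19 ± 0.13. The list as a whole lay 0.01 above all autosomal genes (two-sided permutation p = 0.58). No probe carried the name Myc, and 7 other members were not measured either.

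Of 34 measured genes of the tumour suppressor list, none passed over all genes and 2 passed adjusted over the list alone. With limma, 10 had an unadjusted p under 0.05, as had 4261 of all 20756 gene items. Keap1, on chromosome 9, whose product targets the transcription factor Nfe2l2 for degradation, was at -0.31, -0.26, -0.29 and -0.14 in tumours 1 to 4. Its mean was -0.25 ± 0.08 (SD, n = 4), with an adjusted limma p of 0.19 over all genes and 0.023 over the list alone. It has 1 probe of its own, and in tumour 3 the called loss around it held 53 gene names. With 500 kb flanks it was at -0.15, near the chromosome 9 mean of -0.16. A loss particular to Keap1 is therefore not shown. Cdkn1a, a cell cycle inhibitor gene and p53 target, was at -0.27 ± 0.13 (adjusted p = 0.19, and 0.039 over the list alone) without a called segment. Of its 9 probes, 1 is its own. It was at -0.12, -0.27, -0.43 and -0.25 in tumours 1 to 4, highest in tumour 1 and lowest in tumour 3, as were the correlations with probe GC. Sav1, a Hippo pathway scaffold on chromosome 12, was lost in tumours 1 and 2 (-0.46 in both) with a mean of -0.28 ± 0.21, and Arid2, a chromatin remodelling subunit on chromosome 15, was gained in both (0.25 and 0.36) with a mean of 0.19 ± 0.14; neither passed (adjusted p = 0.19). Its 33 autosomal members lay at -0.0049 relative to all autosomal genes (two-sided permutation p = 0.74). The test leaves out Rps6ka3, a kinase gene on X, at 0.71 in tumour 1 and between -0.09 and 0.04 in the others.

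In the p53 pathway and DNA damage list, 0 of 30 measured genes passed over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05, 15 positive and 15 negative. Xrcc6, a DNA end-joining gene on chromosome 15, lay in gained segments in tumours 1 and 2 (0.25 and 0.21), at -0.03 and -0.01 in the other two. The lowest mean was that of Atr, a damage-sensing kinase gene on chromosome 9, at -0.22 ± 0.20 (SD, n = 4), and the highest that of Parp1, a DNA repair gene, at 0.13 ± 0.21. The list as a whole lay at -0.0068 relative to all autosomal genes (two-sided permutation p = 0.67).

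Of 19 measured large fragile genes, none passed over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. Immp2l, a mitochondrial peptidase gene, was in lost segments of chromosome 12 in tumours 1 and 2 (-0.36 and -0.25), as was Nrxn3, a neurexin gene (-0.33 and -0.23). The only called loss under 5 Mb with an end inside a member was that of Lsamp in tumour 4. Tumour 2 was also low over 11 probes there, at -0.77 ± 0.08 (SE), without a call. Over the whole of Lsamp the mean of tumour 4 was -0.73, a value that rests on dim probes. Averaged over the tumours the gene was at -0.19, against -0.08 under normexp correction, -0.04 with only probes well above background and -0.01 without tumour 4. Its 17 autosomal members lay at -0.02 relative to all autosomal genes (two-sided permutation p = 0.42). The test leaves out Dmd, the dystrophin gene, and Il1rapl1, a synaptic receptor gene, both on X at 0.76 in tumour 1 and between -0.06 and 0.15 in the others.

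Antigen receptor loci were measured because lymphocytes of a spleen reference lose DNA there by rearrangement. The Igh interval, the immunoglobulin heavy chain locus (the end of chromosome 12), had mean log2 ratios of -0.03, 0.03, 0.16 and 0.17 in tumours 1 to 4, with 0 of the 6 loci past limma's test (adjusted p = 0.32 for Igh). Relative to the rest of chromosome 12, a comparison chosen after the data were seen, Igh was higher by 0.27, 0.27, 0.24 and 0.20, a mean of 0.24 ± 0.03 (SD, n = 4), with a two-sided exact sign-flip p of 0.13, the smallest possible. Segments inside it, with the transcript names ENSMUST00000109714 and AK136471, were called gained in tumour 3 (0.38, 114670169 to 116155467) and tumour 4 (0.30, 114670169 to 115910102). The other loci lay near their chromosomes: the difference was -0.02 ± 0.04 for Igk, -0.02 ± 0.05 for Igl, 0.01 ± 0.03 for the T cell receptor alpha and delta locus, -0.01 ± 0.04 for Tcrb and 0.05 ± 0.01 for Tcrg, the last positive in 4 of 4 tumours (exact sign-flip p = 0.13).

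**Figure D4:**
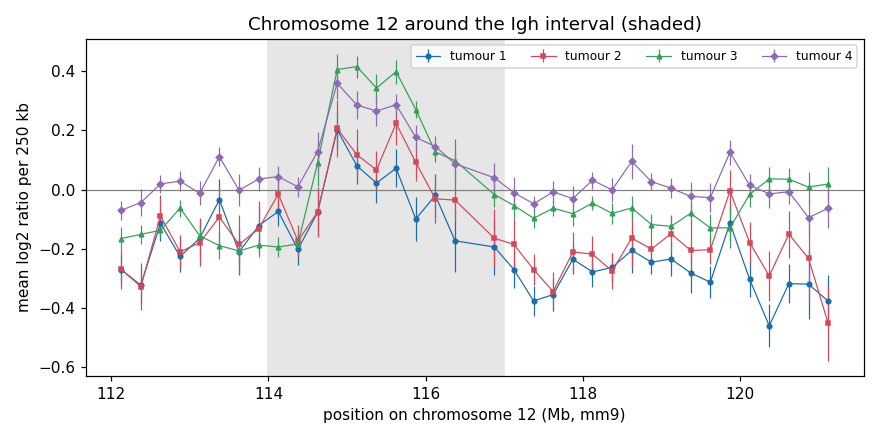
Mean log2 ratio per 250 kb (y axis) along the end of chromosome 12 (x axis, Mb of mm9) in the 4 tumours; points are bins with the SE over probes, and the Igh interval is shaded. All 4 tumours stand higher in the middle of the interval than on either side, by 0.20 to 0.27 over the rest of the chromosome for the whole interval.

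Genes known to differ in copy number between inbred mouse strains were listed in advance, since inherited differences can look like tumour events. Of 12 measured members, Entpd4 passed (-0.57, -0.63, -0.58 and -0.62 in tumours 1 to 4), and it was the only member past the threshold adjusted over the list alone. Glo1 (-0.05 ± 0.04, SE), Dnahc8 (-0.02 ± 0.04), Ide (0.02 ± 0.04) and Skint4 (-0.05 ± 0.03) did not pass, and Nnt was at -0.17 ± 0.06 (adjusted p = 0.22). The other 8 members were not measured under those names.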

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

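The tests of explanations for the sex chromosomes of tumour 1 and for the shared small segments were chosen after the results were seen, except the test of low probes around Trp53, which was set before its value was known. Of 65 values or regions compared over the 4 tumours, 7 had a tumour far from the other 3. For separate values not picked beforehand, chance gives about 1 in 20. That rate does not apply here, since some segments and genes were picked for extreme means in 1 tumour and some items overlap. Chromosome 13 was at -0.20 in tumour 2, against -0.02 to 0.01 in the others. Chromosome 11 was at 0.030 in tumour 1, against -0.046 to -0.034. The Igl locus was at 0.050 in tumour 3, against -0.068 to -0.049, and the Tcrg locus at -0.15 in tumour 2, where all of chromosome 13 was low, against 0.03 to 0.06. The stretch within Lsamp was at -5.50 in tumour 4, and the whole gene at -0.73, both with dim probes there. The stretch of Y was at -4.60 in tumour 3, against -3.60 to -3.41, but all 5 of its probes were dim there, so the gap has no firm size.

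Tumour 1, labelled male, had a raised X (0.81) and a Y at -3.03. A sex mismatch would put Y about as low as the Nlrp1b and Nlrp1c stretch of the same array, if that DNA is missing from all cells: it lay 0.71 above it, but 1.07 above it with dim probes at their bounds, on either side of the limit of 1. Y loss limited to the cells with the changes of chromosomes 9, 12 and 15 is argued against, since it predicts -0.75 (36.2% to 40.3% of cells, if each is a gain or loss of 1 copy) and Y was at most at -2.42. Dim Y probes are argued against, since 100% of them were well above background in the reference channel. A sex mismatch and Y loss in nearly all cells with a gain of X cannot be told apart, because dim probes hide how low Y is.

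The shared small segments at EG214403, Raet1a, Entpd4 and 4922505G16Rik have similar ratios in 4 separate mice. The Nlrp1c stretch, low in all 4, ran from -3.74 to -5.05, with dim probes on each array. In 4 of these 5 regions the ends fell within 1 probe of each other in all tumours. The regions had been kept for like means over the same interval, which favours like ends. The ends therefore count only weakly against separate events in each tumour. Failing probes are argued against by the reference channel, where 100% of the 39 probes of the lost regions were well above background. DNA of another strain, carried along with the engineered Trp53 allele, may account for the Nlrp1c stretch, 1.59 Mb from Trp53. This would need a reference without that DNA. The reference came from littermates per the design, and both channels are labelled Trp53-/-. If these labels hold, the same DNA could lie on both sides and cancel. Within 5 Mb of Trp53, 2.63% of the other probes were under -0.3 in all 4 tumours, against 1.00% on all autosomes. Of 1063 windows of 10 Mb elsewhere, 1.32% had as high a share, but the windows overlap and are not separate places. The regions on other chromosomes were not tested in this way. Entpd4, in the chromosome 14 region, was on the strain list fixed in advance and was its only member past the threshold.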

How the results depend on the processing

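The alternatives with only autosomes, without chromosomes 9, 12 and 15 or small segments, and with Igh relative to its chromosome were chosen after the data were seen. No paired analysis was possible because all tumours form 1 group. A random block for slides gave no value, since only 1 pair of arrays shares a slide. Of 151 alternative values of the results that answer a comparison, 128 kept their direction and side of the threshold or stayed within the tolerance (1.5 times for counts, 1 SD between tumours for the mean altered share), 16 moved and 7 reversed; of 395 for 38 genes, loci and chromosomes, 355 stayed, 20 were weaker, 7 stronger and 13 reversed; of 44 for the altered share of single tumours, 28 moved and 16 stayed within the 95% binomial interval over probes. The SD is wide, so the mean share counts as kept at 13.5% (threshold 0.1), 3.40% (threshold 0.3) and 10.5% (normexp), against 6.62%. With limma, 0 chromosomes and 0 antigen receptor loci passed under all alternatives run (1 chromosome at an unadjusted p under 0.05 before any change), and the permutation p of the similarity stayed at or below 0.0003. Leaving out a tumour gave 0 to 1 bins, 0 to 9 genes, 0 to 1 strain loci and an altered share of 2.83% to 8.79%. Bins changed were 0 under normexp, with probes well above background (which removes the dim probes of the Nlrp1c stretch) and in bins of 2 Mb. Genes changed were 30 with no flank, 6 of them the same genes, and 0 with 500 kb; strain loci were 0 under normexp and with 500 kb. Recurrent bins were 179 at a threshold of 0.1 and 204 in at least 2 of 4 tumours. Values near 0 changed sign. Trp53 was at -0.026 under normexp, -0.0013 after GC correction and -0.022 to 0.033 with a tumour left out. The oncogene list was at -0.0073 with no flank and -0.0014 with 500 kb, the autosomal tumour suppressors at 0.0013 with 500 kb, and the autosomal fragile genes at -0.045 to 0.0032 with a tumour left out. Igk was at -0.014 under normexp, -0.0072 centred on the mode and -0.018 to 0.021 with a tumour left out; the T cell receptor alpha and delta locus at -0.0076 (mode), -0.0024 (GC) and -0.0064 to 0.012; Tcrb at -0.0050 (mode) and -0.012 to 0.020; Tcrg at 0.017 (normexp) and -0.024 to 0.045. Except where stated, the cause was not tested.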

Other observations

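The tests of Igh by position, of Igk with Tcrb and of the probe near Alb were chosen after the results were seen. The GC test of Igh was set before its value was known. A single probe between Alb and Afp, genes of serum proteins made by adult and fetal liver, ranked first of 161460 autosomal probes by its lowest ratio over the tumours (chromosome 5, 90915155 to 90915214), with 1.87, 1.73, 1.44 and 1.54 in tumours 1 to 4 and a mean of 1.65 ± 0.19 (SD, n = 4). The neighbouring probes were lower by at least 1.18 in each tumour. Extra copies of regulatory DNA from this region, such as those in a liver-specific transgene, are a candidate explanation; the labels do not name the line that deleted Trp53, and 1 probe cannot separate this from cross-hybridisation.

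Igh stood above the rest of chromosome 12 in all 4 tumours, by 0.24 ± 0.03 (SD, n = 4), and GC content is argued against, since the difference was 0.25 after GC correction. Reference lymphocytes with rearranged Igh could give ratios that fall along the interval, but the rank correlation with position was 0.07, 0.11, 0.38 and 0.18 in tumours 1 to 4 (mean 0.18), the opposite of the fall that had been looked for. The interval begins before the raised stretch, and from the start of that stretch, a limit chosen after the values by position were seen, the correlation was -0.41, -0.32, -0.58 and -0.51. A fall is partly built into a start at the rise, so rearranged lymphocytes and other sources of the raised ratio cannot be told apart. Rearranged Igk and Tcrb in the reference could raise their ratios as well, and a rise of both in all 4 tumours had been looked for. It was not seen. Relative to the rest of chromosome 6, Igk lay at -0.015 ± 0.043 and Tcrb at -0.013 ± 0.035 (SD), each above 0 in 1 of 4 tumours. With this spread a small rise and none cannot be told apart.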
